A study of Mus musculus with 6 samples.

How the data were processed

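The deposited non-normalized table gave, per its column names, 1 intensity and 1 detection p-value for each of 25697 probes on each of 6 arrays. The intensities were linear, not background-subtracted and not matched between arrays. A second deposited table gave values processed by the authors, which from their range were on a log2-like scale, with a median of 7.77 on each array. The transform, the normalization and any centring are not given in the sources used here, and it was used only as an alternative. On the 3927 brightest probes, after each probe was centred, each array correlated at 0.974 to 0.989 with its own column of the authors' table. With any other column it correlated at no more than 0.833. The submitters' processing notes name GenomeStudio 2011.1, lumi and limma, without a role or order for each.

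The intensities were background-corrected with neqc in limma 3.58.1 (R 4.3.3), which fits a normal-exponential model with the background inferred from the detection p-values, adds an offset of 16, takes log2 and applies quantile normalization. Probes with a detection p under 0.05 on at least 2 of the 6 arrays were kept. Of all probes, 23978 carried 1 gene symbol, 1719 none and 0 several; 23962 were matched to the reference gene table by Entrez number, which changed 0 symbols. Of the named probes, 12452 passed the filter, and the brightest probe of each gene was kept, giving 9010 genes. Among 2423 genes with more than 1 probe past the filter, 985 had a changed probe, 344 had all probes changed to the same side and 3 had probes changed to opposite sides.

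A linear model with a mean for each of the 3 groups was fitted with lmFit, followed by eBayes with trend and robust off (prior df 3.62, prior SD 0.2, residual df 3). The contrasts were miR-128 minus the mean of both scrambled groups, miR-128 minus each scrambled group, and shScr2 minus shScr1. The limma moderated statistic was tested on both sides and p was adjusted by Benjamini-Hochberg over the 9010 genes, with a threshold of 0.05. Each value after ± is the standard error of limma. A gene undetected on all scrambled arrays, on all miR-128 arrays or, between the scrambled groups, in either group was given only a lower bound on its fold change, taken from the lowest detected level after neqc. The bound holds for that background correction alone. A gene undetected in shScr1 only was given its change against shScr2. The comparisons, gene lists, rule for named genes and alternatives were fixed before the data were examined.

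For gene lists, camera in limma was run with a preset correlation of 0.01, adjusted over the 26 of 29 lists with at least 5 measured members. It was repeated with an estimated correlation, with which 0 lists passed, and with fry, with which 16 passed, against 8 in the first run. The run with an estimated correlation tests on the 3 residual degrees of freedom, which makes passing hard. The estimate was −0.061 for contractile genes, −0.027 for cholesterol synthesis and 0.003 for ribosomal proteins, below the preset. Their unadjusted p in camera still rose to 0.0074, 0.0144 and 0.0147, so their loss does not come from correlated members. The estimate was 0.632 for the cell cycle and 0.417 for interferon, whose unadjusted p in camera rose further, to 0.251 and 0.217. With the preset, the unadjusted p was 1.24e-09 for the cell cycle and 1.16e-09 for contractile genes. It was 9.92e-07 for interferon and 2.03e-06 for cholesterol synthesis. Correlated members thus add to the loss for the cell cycle and interferon, beyond the few degrees of freedom. Camera compares a list with the other genes, while fry does not. The lists covered contractile genes, regulators of smooth muscle phenotype, modulated or synthetic smooth muscle genes, collagens and matrix, matrix proteases, cell cycle, p53 and senescence, interferon, inflammation, cholesterol synthesis and efflux, TGF-beta, YAP, growth factor signalling, chromatin factors, published miR-128 targets, miRNA processing, host genes of miR-128, stress responses, hypoxia, oxidative phosphorylation, ribosomal proteins, lysosome, NRF2 targets, and markers of endothelial cells, leukocytes, fibroblasts, adipocytes and Schwann cells.

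The genes named were the 12 highest and the 12 lowest in log2 change among genes past the threshold whose miR-128 arrays both lay beyond all 4 scrambled arrays, 12 genes fixed by name (Phf6, Klf4, Myh11, Acta2, Tagln, Cnn1, Myocd, Srf, Bmi1, E2f3, Arpp21 and R3hdm1), the members of each list with the smallest adjusted p, and the genes of largest change between the scrambled groups. Ccnd2, Tnfrsf10b, Synm, Cald1, Des, Mx2, Bace2, Egr2, Ntrk3, Pparg and Mbp were named after their values were seen, since they were exceptions or completed a small count.

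The model and list steps were tested on simulated log2 values, in which genes varied independently, with 200 changed genes. Of 50 genes planted at each size, 2% were recovered at a log2 change of 0.5, 52% at 1, 96% at 2 and 100% at 3, with 4 false calls among 129. Between simulated scrambled groups 0 unchanged genes were called by limma. A list of 20 genes shifted by 0.5 had an adjusted p of 1.23e-09 in camera, and 0 of 100 unchanged lists were called. In the data far more genes were called and the miR-128 arrays spread more, so these rates need not carry over. Lists of genes that vary together were not simulated.

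Arrays with the same replicate letter deviated together: the correlation across genes of the differences between replicates A and B was 0.122 for shScr1 with shScr2, 0.129 for shScr1 with mir128 and 0.152 for shScr2 with mir128. All 3 were over 0.1, which was taken, before the fits were compared, as a sign that the letters pair the arrays. The main fit, fixed earlier, has no term for the letter, so its p-values are unpaired, and the letter entered as a block in an alternative fit, whose value is given where it changed the call of a named gene or moved a count. The labels do not say what the letters share. Before normalization, replicate A had a higher mean intensity than replicate B in shScr1 (477 against 432), shScr2 (447 against 408) and mir128 (633 against 446). Whether this shared brightness, rather than pairing, gave the correlations was not tested.

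The alternatives were normexp background correction with an offset of 50, no background correction, scaling to a common median, the authors' values, no detection filter, detection on all 6 arrays, all probes, trend and robust eBayes, pooled scrambled groups, the replicate letter as a block, and each array left out in turn. The mean over the detected probes of a gene was added after the data were seen, as were the values of each Acta2 probe against each scrambled group. Blocking by slide was not run because the tables give no slide, and shifts of genes with miR-128 seed sites were not analysed here because no transcript sequence was at hand.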

Results

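Primary vascular smooth muscle cells from C57BL/6J mice were transduced with lentivirus carrying miR-128 or a scrambled miRNA, and their mRNA was measured on Illumina bead arrays of 25697 probes. All samples shared an age of 8 weeks, 2 days of puromycin and harvest at 5 days. The 6 arrays formed 3 groups of 2 biological replicates, named A and B. The group called mir128 here received miR-128. The groups titled shScr1 and shScr2 both carry the label scrambled miRNA and served as controls. Between 11589 and 12343 probes were detected on 5 of the arrays, and 13277 on mir128 replicate A, which was also the brightest array, with an upper quartile of intensity of 373 against 201 to 252 on the others. After normalization, replicate arrays correlated across genes at r = 0.993 in shScr1, 0.991 in shScr2 and 0.974 in mir128, and miR-128 arrays correlated with scrambled arrays at 0.933 to 0.954. Genes are not independent replicates, and the small number of arrays limits the precision of every value.

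The main comparison asked which genes changed when miR-128 was overexpressed, taking both scrambled groups as the control. Smooth muscle contractile genes were among the largest rises. Actg2, the enteric smooth muscle actin, was 35.3-fold higher (log2 change 5.14 ± 0.22, SE; adjusted p = 0.000138), and Tagln, which encodes the actin-binding protein transgelin, was 26.8-fold higher (4.74 ± 0.17; adjusted p = 0.000101), although Tagln was at 3.05 without background correction. On the authors' values, whose scale is compressed, the log2 changes were 2.89 and 1.82. Interferon-response and p53-response genes also rose, while genes of the cell cycle, of cholesterol synthesis and of the cytosolic ribosome fell. None of these list calls held with an estimated correlation, with an adjusted p = 0.649 for interferon, 0.443 for p53, 0.649 for the cell cycle, and 0.127 for cholesterol synthesis and for ribosomal proteins, each with an estimated correlation. That run has few degrees of freedom, and for cholesterol synthesis and ribosomal proteins the estimated correlation was below the preset. For the cell cycle and interferon the estimated correlation was 0.632 and 0.417, so correlated members add to the loss there. With the brightest probe of each gene, the steepest falls were in the ribosomal protein genes Rplp0, 11.5-fold lower, and Rpl29, 10.7-fold lower (adjusted p = 0.000101 for each). Rplp0 was at −2.09 on the log2 scale with the mean over its probes.

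Of 9010 genes tested, 2665 passed the test, of which 1427 were higher and 1238 lower with miR-128, and 1021 of them changed at least 2-fold. The fit shares 1 spread over the 3 groups. The SD of the difference between replicates A and B was 0.524 in mir128 against 0.277 in shScr1 and 0.304 in shScr2. The errors of the miR-128 comparisons may thus be too small. Both miR-128 arrays lay beyond all 4 scrambled arrays for 4246 genes, 47.1% of those tested, where chance gives 13.3% if all 6 arrays are exchangeable, without regard to the replicate letters. When each array was scaled to a common median instead of being quantile normalized, the median of all genes moved to 0.19 and the calls split into 1552 higher and 568 lower. The count fell to 1260 without shScr1 replicate A, 1267 without shScr1 replicate B, 1409 without shScr2 replicate A and 1398 without shScr2 replicate B.

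Among the 12 genes with the largest rises, Lmcd1, a LIM and cysteine-rich domain protein, was 28.2-fold higher (log2 change 4.82 ± 0.23; adjusted p = 0.000206). Lims2, an adaptor of integrin adhesions, was 21.2-fold higher (4.40 ± 0.13; adjusted p = 0.000101), and Acta1, skeletal muscle actin, passed as well (adjusted p = 0.00179). Acta1 was detected on both shScr2 arrays and on no shScr1 array, and was higher than shScr2 by 3.28 on the log2 scale. Asb2, a muscle ubiquitin ligase subunit, and Mustn1, a musculoskeletal nuclear protein, were not detected on any scrambled array and were at least 11.4-fold and at least 8.22-fold higher after background correction. Without it their log2 changes were 1.99 and 1.70, and those of Lmcd1, Fam210b and Lmod1 were 3.13, 2.08 and 1.72. Gstt1, Fam210b, Parm1 and Nppb (brain natriuretic peptide), with log2 changes of 3.61 ± 0.27, 3.59 ± 0.49, 3.58 ± 0.13 and 3.52 ± 0.32, and Lmod1 completed the 12. Nppb was higher by 4.69 against shScr1 and by 2.34 against shScr2, and Parm1 by 4.61 and 2.55. The SD of the miR-128 arrays was 1.30 for Fam210b and 1.25 for Acta1, so these sizes are imprecise. Actg2, Acta1 and Acta2 are near-identical actin genes, so signal shared between their probes cannot be excluded.

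The 12 largest falls, after Rplp0 (log2 change −3.53 ± 0.14 with its brightest probe, and −0.66 with a dim one) and Rpl29 (−3.42 ± 0.13), included the histone genes H3c7 (−2.87 ± 0.15; adjusted p = 0.000292) and H2ac21 (−2.55 ± 0.46; adjusted p = 0.00967). Histone genes of a family are near-identical in sequence, so these names are uncertain. H3c7 was detected on 1 of the 2 miR-128 arrays, and H2ac21 was at −1.65 without miR-128 replicate A. Tcf19, a growth-regulated transcription factor gene, was at −2.64 ± 0.23, and Snrnp70, a U1 snRNP protein gene, was at −2.62 ± 0.41. The SD of the miR-128 arrays was 1.12 for Snrnp70, so its size is imprecise. Stt3b, a catalytic subunit of oligosaccharyltransferase in the endoplasmic reticulum, fell by 2.52, and Lman2, a cargo lectin of the early secretory pathway, fell by 2.33 on the log2 scale. Ydjc, Pus7l, Grcc10 and Tmem30a completed the 12, with log2 changes of −2.61, −2.55, −2.54 and −2.34. Without background correction H3c7, Grcc10 and Tmem30a were at −1.33, −1.38 and −1.40.

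Contractile smooth muscle genes rose as a group. Of 15 measured members, 12 were higher with miR-128 and none was lower, and the list median was 1.37 on the log2 scale. Adjusted over the list alone, 13 members were higher. Besides Tagln and Actg2, Lmod1, a leiomodin that nucleates actin filaments, passed as well (adjusted p = 0.000205). Lmod1 was detected on 1 shScr2 array and on no shScr1 array, and was higher than shScr2 by 3.29 on the log2 scale. Mrvi1, a substrate of cGMP-dependent kinase, and Myh11, the smooth muscle myosin heavy chain (adjusted p = 0.00284), were detected on both miR-128 arrays and on no scrambled array, and were at least 4.60-fold and at least 2.06-fold higher after background correction. Without it their log2 changes were 1.09 and 0.51. With the 3 such members set at their bound, the list median was 1.28, and without a detection filter, which adds undetected members, it was 0.56. The 3 members that did not pass, Synm, Cald1 and Des, are named because they were the exceptions. The list shift had an adjusted p of 1.61e-08 in camera with its preset correlation, and adjusted p = 0.127 with an estimated correlation. The estimated correlation was −0.061, below the preset, so this loss does not come from correlated members.

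The probes of Acta2, the alpha smooth muscle actin gene, disagreed in size. The brightest probe, which the probe rule selects, rose 1.62-fold (log2 change 0.70 ± 0.17; adjusted p = 0.0235) from a mean of 13.90 to 14.60, near the top of the signal range, while 3 other probes rose by 2.93, 3.38 and 3.58. The mean over the Acta2 probes rose by 2.65 (adjusted p = 0.000337). Against shScr2 the 3 other probes rose by 2.32, 2.75 and 2.93 (adjusted p = 0.00175, 0.00182 and 0.00415 over all probes), and against shScr1 by 3.54, 4.01 and 4.23. The brightest probe was at 1.12 against shScr1 (adjusted p = 0.0106) and at 0.27 against shScr2 (adjusted p = 0.347). In the main comparison it no longer passed with arrays scaled to a common median (adjusted p = 0.0772), with the scrambled groups pooled (adjusted p = 0.135), or, at log2 changes of 0.67, 0.73, 0.68 and 0.70, without shScr1 replicate A, shScr1 replicate B, shScr2 replicate A or shScr2 replicate B in that order. Cnn1, the calponin gene, was detected on 0 of the 6 arrays and Myocd, the myocardin gene, on at most 1, so neither was tested. Srf, the transcription factor that drives contractile genes with myocardin, was 2.27-fold higher (log2 change 1.18 ± 0.16; adjusted p = 0.00357) with its bright probe, while a dim probe was at 0.08, and the mean of both probes did not pass (0.63; adjusted p = 0.0579).

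**Figure D1:**
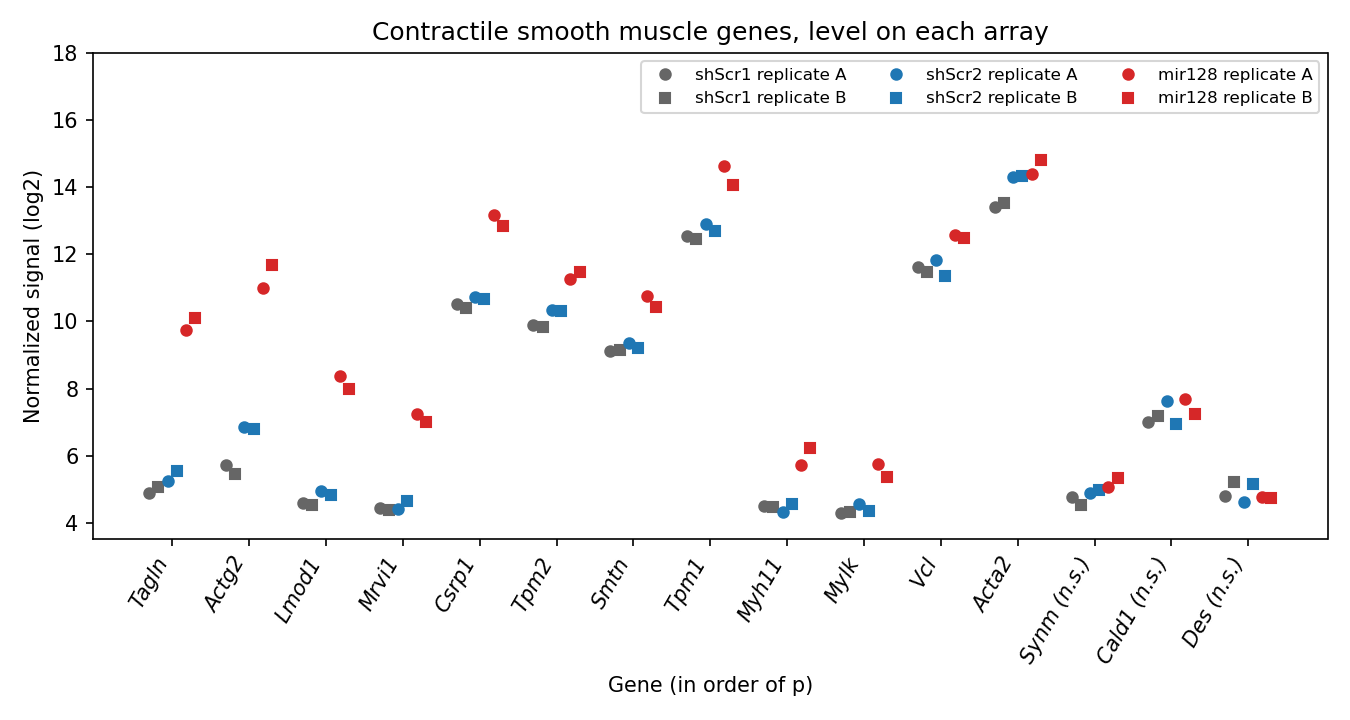
Normalized signal (log2, vertical axis) of the 15 measured contractile smooth muscle genes (horizontal axis, in order of p) on each of the 6 arrays; colours mark the groups, circles replicate A and squares replicate B, and n.s. marks the 3 genes that did not pass the test. Both miR-128 arrays lie above all 4 scrambled arrays for the 12 genes that passed.

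Genes of the cell cycle and DNA replication fell as a group, with 26 of 40 measured members lower, 1 higher and a list median of −1.15. Adjusted over the list alone, 30 were lower and 1 higher. Top2a, topoisomerase II alpha, fell 4.16-fold (log2 change −2.06 ± 0.24; adjusted p = 0.00240), and Cdc6, which licenses replication origins, fell 3.08-fold (−1.62 ± 0.21; adjusted p = 0.00306). Rrm2, a ribonucleotide reductase subunit, and Ccne2, cyclin E2, were at −1.42 and −1.79. Ccne2 was at −0.97 without background correction, and Cdc6 at −0.97 with the mean over its probes. The other Cdc6 probe in that mean was near background, detected on 2 scrambled arrays and 0 miR-128 arrays. The member that rose was Ccnd2, cyclin D2 (0.65 ± 0.14; adjusted p = 0.0153), named after its values were seen because it was the exception. The list had an adjusted p of 1.61e-08, and adjusted p = 0.649 with an estimated correlation; fry, which asks only whether the members move on balance to 1 side, gave an adjusted p of 0.0570. The median was −1.73 in miR-128 replicate A and −0.65 in replicate B. Without replicate A the list median was −0.65, and without replicate B it was −1.74, with the list past the threshold each time.

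Targets of p53 and senescence genes rose, with 12 of 21 measured members higher and 1 lower and a list median of 0.61. Adjusted over the list alone, 12 were higher and 2 lower. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, was 3.05-fold higher (log2 change 1.61 ± 0.14; adjusted p = 0.000990). Cdkn2b, which encodes the inhibitor p15, was 3.80-fold higher (1.93 ± 0.20; adjusted p = 0.00182), and Phlda3, a p53-induced inhibitor of Akt, was 2.68-fold higher (1.42 ± 0.13; adjusted p = 0.00146). The member that fell, Tnfrsf10b (−0.84), was named after its values were seen. The list had an adjusted p of 0.000760, and adjusted p = 0.443 with an estimated correlation.

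Interferon-response genes rose, with 16 of 29 measured members higher, none lower and a list median of 1.08, or 0.85 with Mx2, which no scrambled array detected, set at its bound. Adjusted over the list alone, 17 were higher. Ifit3, an interferon-induced antiviral protein, was 9.30-fold higher (log2 change 3.22 ± 0.25; adjusted p = 0.000818), Ifi27l2a was 8.28-fold higher (3.05 ± 0.20; adjusted p = 0.000504) and Gbp2, a guanylate-binding protein, was 7.88-fold higher (2.98 ± 0.17; adjusted p = 0.000342). Gbp2 was at 1.86 with the mean over its probes, where the other probe was dim and detected on 0 scrambled arrays. The list median was 0.59 without background correction and 0.56 without a detection filter. The list had an adjusted p of 8.60e-06, and adjusted p = 0.649 with an estimated correlation. Its median was 0.73 in miR-128 replicate A and 1.38 in replicate B, while the contractile median was 1.36 in replicate A and 1.37 in replicate B.

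**Figure D2:**
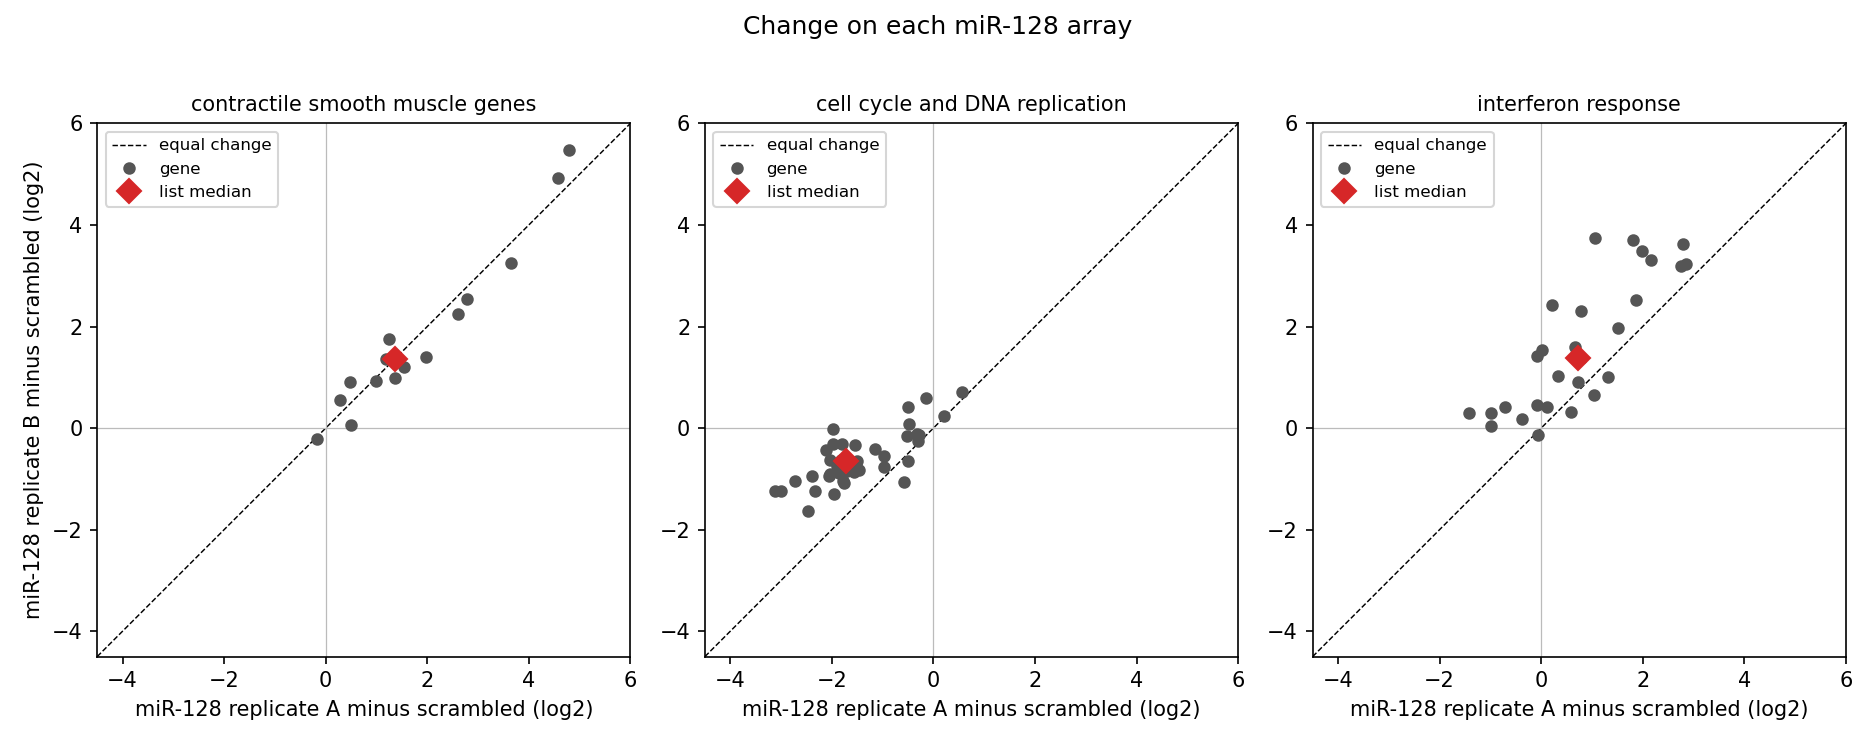
Change of each list member on miR-128 replicate A (horizontal axis) and replicate B (vertical axis), each as the normalized log2 signal minus the mean of the scrambled groups, for 3 gene lists; the dashed line marks equal change and the red diamond the list median. The contractile medians were 1.36 and 1.37, the cell cycle medians −1.73 and −0.65, and the interferon medians 0.73 and 1.38, in replicates A and B in that order.

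Genes of cholesterol synthesis fell, with 12 of 17 measured members lower, none higher and a list median of −0.85. Adjusted over the list alone, 12 were lower. Msmo1, a sterol C4 demethylation enzyme, fell 3.01-fold (log2 change −1.59 ± 0.16; adjusted p = 0.00173), Srebf2, the transcription factor gene that controls the pathway, fell 2.42-fold (−1.28 ± 0.15; adjusted p = 0.00246), and Sqle, squalene epoxidase, fell 2.15-fold (−1.10 ± 0.13; adjusted p = 0.00272). The list had an adjusted p of 1.06e-05, and adjusted p = 0.127 with an estimated correlation. Cytosolic ribosomal protein genes fell as well, with 11 of 21 lower, none higher and a median of −0.53, and 12 lower adjusted over the list alone. After Rplp0, the lowest were Rpl13a (−1.46 ± 0.14), Rpl27a (−1.42 ± 0.16) and Rpl4 (−1.25 ± 0.14). This list had an adjusted p of 1.06e-05, and adjusted p = 0.127 with an estimated correlation. A second, dim probe of Rplp0, detected on 3 of the 4 scrambled arrays and on 0 of the miR-128 arrays, was at −0.66, so that Rplp0 was at −2.09 with the mean over its probes, and a second probe of Rpl29, which is not on the list, was at −3.46.

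Targets of YAP and TEAD rose, with 7 of 16 measured members higher, none lower and a median of 0.54, and 9 were higher adjusted over the list alone. Gadd45a, a growth arrest and DNA damage gene, was 9.86-fold higher (SE 0.20 on the log2 scale; adjusted p = 0.000432), and Ankrd1, a muscle ankyrin repeat protein, was 4.94-fold higher (2.30 ± 0.27; adjusted p = 0.00243). The list median was 0.34 without background correction and 0.35 without a detection filter. The list had an adjusted p of 0.00637, and adjusted p = 0.385 with an estimated correlation. With the preset correlation it passed in camera against shScr1 (adjusted p = 0.000742) and not against shScr2 (adjusted p = 0.0991). The TGF-beta and SMAD list had 8 of 26 members higher, 2 lower and a median of 0.41, with the same counts adjusted over the list alone. Tgfb3 was 3.82-fold higher (1.93 ± 0.16; adjusted p = 0.000929) and the receptor gene Tgfbr1 was 2.45-fold higher (1.29 ± 0.16; adjusted p = 0.00284), while Ltbp4, a latent TGF-beta binding protein, was 2.67-fold lower (−1.42 ± 0.17; adjusted p = 0.00272), or at −0.84 without background correction. This list passed narrowly, with an adjusted p of 0.0455, and adjusted p = 0.385 with an estimated correlation. It did not pass with arrays scaled to a common median (0.1498), with the authors' values (0.0687), with detection on all 6 arrays (0.0748), with the scrambled groups pooled (0.0603), with the mean over the probes of each gene (0.0754), or without shScr1 replicate A (0.0568), shScr2 replicate A (0.0611) or shScr2 replicate B (0.0501), each an adjusted p. Without miR-128 replicate A its median was 0.23, still past the threshold.

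**Figure D3:**
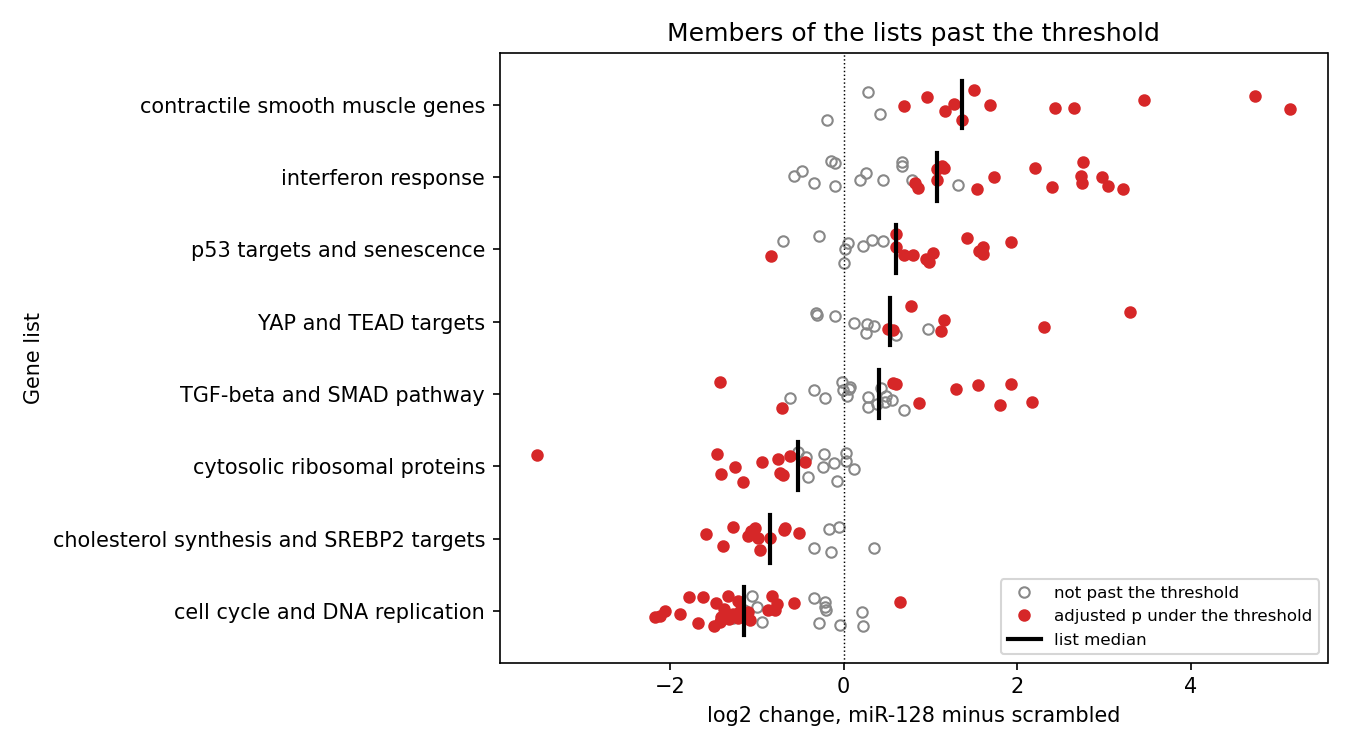
log2 change with miR-128 against the scrambled groups (horizontal axis) of the members of the 8 gene lists past the threshold (vertical axis); filled points passed the test, open points did not, and the black bar is the list median. Medians ran from −1.15 for the cell cycle list to 1.37 for the contractile list.

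Published miR-128 targets did not pass as a list in camera (20 measured, median −0.19, adjusted p = 0.711), with 5 members higher and 6 lower, and 6 higher and 6 lower adjusted over the list alone. Egfr, the epidermal growth factor receptor, was higher (log2 change 1.72 ± 0.16; adjusted p = 0.00146; 1.09 with the mean over its probes), and Tgfbr1 was also higher. Casc3, an exon junction complex gene, was 2.36-fold lower (−1.24 ± 0.16; adjusted p = 0.00316), and Phf6, which encodes a chromatin-associated PHD finger protein, was 2.06-fold lower (−1.04 ± 0.16; adjusted p = 0.00547). A second Phf6 probe was detected on 0 arrays. Bmi1, a Polycomb gene, was at −0.21 (adjusted p = 0.662), at −0.84 (adjusted p = 0.0135) without miR-128 replicate B and at 0.41 without replicate A. E2f3 was at 0.22 (adjusted p = 0.395), at 0.09 without shScr2 replicate A and 0.35 without shScr2 replicate B. Klf4, a transcription factor gene of smooth muscle phenotype change, was at −0.14 (adjusted p = 0.625), and its 2 other probes were at −0.12 and −0.01. Without miR-128 replicate A or B the Klf4 value was −0.41 or 0.13, not past the threshold. R3hdm1, a host gene of miR-128, was near background. Its brighter probe, detected on 3 scrambled arrays and on no miR-128 array, did not pass (adjusted p = 0.144), except without miR-128 replicate B (adjusted p = 0.0419), and is given no fold change. Its other probe was detected on 1 scrambled and 1 miR-128 array. The other host gene, Arpp21, was detected on 0 arrays. The arrays carry no value for miR-128 itself used here, so its overexpression was not checked.

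The other tested lists did not pass in camera. Of these, fry, which does not compare a list with other genes, passed the lists of phenotype regulators, collagens and matrix, inflammatory genes, LXR targets and hypoxia (adjusted p = 0.0261 for each), and of growth factor signalling and stress responses (adjusted p = 0.0273 for each). Regulators of smooth muscle phenotype had 6 of 21 members higher and 2 lower (median −0.02, adjusted p = 0.483), among them Klf5 (log2 change 1.32) and Pdgfrb (1.82, or 1.00 without background correction). Genes of modulated or synthetic smooth muscle cells had 4 of 15 higher and 1 lower (0.10, adjusted p = 0.391), Sparc (1.13) among them. Tnc, the matrix protein tenascin C, was 10.6-fold higher, or at 1.91 on the log2 scale with the mean over its probes. That mean includes dim Tnc probes near background, at −0.09 and 1.05. Fibrillar collagens and matrix had 6 of 24 higher and 2 lower (0.18, adjusted p = 0.389), including Col4a2 (1.88) and Col4a1 (1.51), and matrix proteases and inhibitors had 4 of 17 higher and 3 lower (0.05, adjusted p = 0.721), including Mmp23 (−1.85) and Mmp11 (2.18), which were at −0.83 and 1.41 without background correction. Growth factor and PDGF signalling had 10 of 23 higher and 5 lower (0.23, adjusted p = 0.389), with Egfr and Igf1 (1.15) higher and Vegfb (−1.49) lower. Inflammatory and NF-kB targets had 5 of 20 higher and 1 lower (0.37, adjusted p = 0.134), with Cxcl1 at −2.22 and Nfkbia at 0.92. Cholesterol efflux and LXR targets had 3 of 11 higher and 3 lower (−0.18, adjusted p = 0.391), with Abca7 lower (−1.82, or −1.20 without background correction) and Lpl, described below, among those higher. Stress-response genes had 9 of 27 higher and 6 lower (0.11, adjusted p = 0.515), with Nupr1 (2.18) and Ddit3 (1.65) among those higher. Chromatin and DNA methylation factors had 4 of 25 higher and 4 lower (−0.06, adjusted p = 0.711), with Dnmt1, the maintenance DNA methyltransferase, at −1.87. miRNA processing and silencing genes had 1 of 15 higher and 3 lower (0.02, adjusted p = 0.711), with Dicer1 at 1.18 and Ago2, Tnrc6a and Ddx6 at −0.86, −0.59 and −0.89. A second Tnrc6a probe, detected on all 6 arrays, was at −0.06. The 3 lower ones missed the threshold without shScr1 replicate A (−0.78, −0.58 and −0.92), shScr1 replicate B (−0.94, −0.60 and −0.87) or shScr2 replicate A (−0.72, −0.52 and −0.83), Tnrc6a and Ddx6 also without shScr2 replicate B (−0.64 and −0.93), and Ago2 and Ddx6 without miR-128 replicate A (−0.81 and −0.49). With arrays scaled to a common median Ago2 and Tnrc6a did not pass either. Hypoxia and glycolysis had 1 of 20 higher and 4 lower (−0.02, adjusted p = 0.708), with Tpi1 at −1.98 and Pdk1 at −1.16 (−0.65 without background correction), the latter not past the threshold with the scrambled groups pooled. Lysosome and autophagy had 5 of 26 higher and 2 lower (0.17, adjusted p = 0.437), with Sqstm1 at 1.47. NRF2 targets had 3 of 19 higher and 1 lower (0.28, adjusted p = 0.133). Gstm1 was at 1.31, or 0.76 with the mean over its probes, which includes a dim probe at 0.21. It also missed the threshold with those groups pooled. The NRF2 list passed without miR-128 replicate B (median 0.53, adjusted p = 0.00311) and without a detection filter (adjusted p = 0.0215), and was at 0.05 without replicate A. Oxidative phosphorylation had 2 of 28 (0.04, adjusted p = 0.991), Cyc1 at −0.46 and Ndufa1 at 0.55 (0.33 without miR-128 replicate A), and neither passed with the replicate letter as a block (adjusted p = 0.0555 and 0.0546). The medians of these lists lay between −0.18 and 0.37, and several moved by more than 1.5 times when 1 array was left out. The test pointed up for the phenotype regulators, whose median was below 0, and down for miRNA processing and oxidative phosphorylation, whose medians were above 0.

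Lists of markers of other cell types did not pass in camera, while fry passed the leukocyte list (adjusted p = 0.0261) and the fibroblast list (adjusted p = 0.0273). Endothelial markers had 1 of 6 measured members past the threshold (Egfl7, log2 change −1.04; list adjusted p = 0.721), macrophage and leukocyte markers had 3 of 7 higher and 1 lower (Lyz1 at 1.92, Lyz2 at 1.32 and Cd14 at −1.12; list adjusted p = 0.391), and adventitial fibroblast markers had 4 of 13 higher and 3 lower (Mfap5 at 2.53 and Has1 at −1.33; list adjusted p = 0.770). Lyz1 was at 1.13, Lyz2 at 0.48 and Has1 at −0.77 without background correction, and Lyz2 did not pass on the authors' values. Laptm5, also among those higher, was detected on no scrambled array (at least 1.21-fold higher) and missed the threshold without shScr1 replicate A, shScr1 replicate B, shScr2 replicate A or shScr2 replicate B (adjusted p = 0.0793, 0.0772, 0.0683 and 0.0734). Cd14 missed the threshold with arrays scaled to a common median. Adipocyte and Schwann cell or neuronal markers had 3 measured members each, too few for the test. Lpl (1.63, or 1.05 without miR-128 replicate B; not past the threshold with the scrambled groups pooled or on the authors' values) and Pparg (0.84) were higher and Mbp (−0.58) was lower.

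Each scrambled group was also taken as the control on its own. Contractile genes were higher against either group, with list medians of 1.49 against shScr1 (adjusted p = 4.26e-09) and 1.29 against shScr2 (adjusted p = 5.62e-08). Cell cycle genes were lower against either, with medians of −1.14 (adjusted p = 6.27e-07) and −1.19 (adjusted p = 5.40e-09). Interferon genes were higher, with medians of 0.85 against shScr1 (adjusted p = 0.000928) and 1.21 against shScr2 (adjusted p = 5.62e-08). Cholesterol synthesis genes were lower, with medians of −1.22 against shScr1 (adjusted p = 2.04e-07) and −0.42 against shScr2 (adjusted p = 0.00642). Medians of the p53 list were 0.60 and 0.61 (adjusted p = 0.000928 and 0.00102) and those of the ribosomal protein list −0.51 and −0.55 (adjusted p = 1.90e-05 and 1.40e-05). The YAP list passed against shScr1 (0.72, adjusted p = 0.000742) and not against shScr2 (0.28, adjusted p = 0.0991), and the TGF-beta list passed against shScr2 (0.36, adjusted p = 0.0429) and not against shScr1 (0.45, adjusted p = 0.102); the differences between these pairs of values were not tested. With an estimated correlation none of the lists passed against either group, with adjusted p from 0.115 to 0.706 against shScr1 and from 0.194 to 0.492 against shScr2 for those named here.

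Against shScr1, 2093 genes passed the test, 1120 higher and 973 lower. Against shScr2, 2008 passed, 1090 higher and 918 lower. With arrays scaled to a common median the split was 909 higher and 445 lower against shScr1, and 1267 higher and 343 lower against shScr2. The count against shScr1 fell to 284 and 287 without shScr1 replicate A or B and to 1214 and 1179 without shScr2 replicate A or B, and was 3160 without miR-128 replicate B. The count against shScr2 fell to 1022 and 1010 without shScr1 replicate A or B, and to 341 and 330 without shScr2 replicate A or B.

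The scrambled groups were compared with each other to give the background between controls. Lims2 and Parm1 were among the genes that rose most with miR-128, and were also higher in shScr2 than in shScr1. Lims2 was 3.61-fold higher (log2 change 1.85 ± 0.15, adjusted p = 0.0145) and Parm1 4.15-fold higher (2.05 ± 0.16, adjusted p = 0.0135). Nppb, another of those genes, was higher in shScr2 by 2.35 ± 0.36 on the log2 scale and did not pass in limma (adjusted p = 0.0902). Gdf10, a BMP-family ligand gene, was 12.9-fold lower in shScr2 (−3.68 ± 0.33; adjusted p = 0.0191) with detection on 1 of its 2 arrays. Fmo1, a flavin monooxygenase gene, was not detected on either shScr2 array and was at least 6.59-fold lower after background correction (adjusted p = 0.0135). Without that correction the log2 changes of Lims2, Parm1, Gdf10 and Fmo1 were 1.09, 1.35, −1.97 and −1.35. Dcn, the proteoglycan decorin, was 5.29-fold lower (−2.40 ± 0.19; adjusted p = 0.0135), and Bace2, Egr2 and Ntrk3 were the remaining 3 genes past the threshold, all lower.

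In all, 8 of 9010 genes passed between the scrambled groups, 2 higher and 6 lower in shScr2. In that fit 1046 genes had an unadjusted p under 0.05 in limma. Since the fit shares 1 spread with the more variable miR-128 arrays, 8 may be too low as the background between controls. With the replicate letter as a block, 1 gene passed, Fmo1, and Lims2, Parm1 and Dcn also missed the threshold with arrays scaled to a common median (adjusted p = 0.0621 for each). Lims2 missed it on the authors' values (adjusted p = 0.0536), Gdf10 without a detection filter (adjusted p = 0.05003) and Parm1 with the mean over its probes (adjusted p = 0.0536). The count was 362 without miR-128 replicate A and 252 without miR-128 replicate B, and limma called 0 genes without any single scrambled array, where 507 to 605 genes had an unadjusted p under 0.05. As lists, interferon-response genes (median −0.52, adjusted p = 1.01e-07), cholesterol synthesis genes (−0.64, adjusted p = 2.27e-09), stress-response genes (−0.49, adjusted p = 2.28e-06), LXR targets (−0.59, adjusted p = 0.00211), hypoxia and glycolysis genes (−0.30, adjusted p = 0.00283) and collagens and matrix genes (−0.19, adjusted p = 0.0196) were lower in shScr2. Contractile genes (0.24, adjusted p = 0.00284) and YAP targets (0.33, adjusted p = 0.0107) were higher in shScr2. No member of these 8 lists passed the test by itself, and with an estimated correlation none of the lists passed, with adjusted p from 0.156 for cholesterol synthesis to 0.425 for interferon response.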

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

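The tests on the choice of the scrambled group and on Rpl29 and Rplp0 were chosen only after those results were seen.

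Probes without a gene name lie outside the comparisons of genes. Of 784 such probes that were detected, 209 changed with miR-128, 99 higher and 110 lower, which flagged them as signal in data that the gene comparisons do not use. They were tested in the same way and were not traced to genes.

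Cell cycle and interferon genes were both lower on miR-128 replicate A than on replicate B. Processing of the brightest array stays open: the smallest gap between replicates A and B in 4 other processings was −0.44 (−0.4356) for cell cycle genes and −0.25 (−0.2527) for interferon genes, both on the authors' compressed scale. In the other 3 processings the gap was −0.68 to −0.75 for cell cycle genes and −0.43 to −0.72 for interferon genes, so none removed it, but the bound set for exclusion was not met on the authors' scale. A signal-dependent distortion shared by genes of the same level is argued against, since both gaps lay at percentile 0 of 10000 random lists matched on mean expression. A difference between the cultures of the replicates, such as their growth, may remain, and was not tested because the labels describe none.

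Interferon and cholesterol synthesis genes also differed between the scrambled groups, in camera with a preset correlation (adjusted p = 0.425 and 0.156 with an estimated correlation). The choice of the scrambled group is argued against as the whole source of the miR-128 result, since both lists passed in the same direction against either group, with a larger adjusted p of 0.000928 for interferon and 0.00642 for cholesterol synthesis in camera with its preset correlation. With an estimated correlation neither list passed against shScr1 or shScr2 (adjusted p = 0.706 and 0.492 for interferon, 0.115 and 0.362 for cholesterol synthesis), so this holds only for the preset. The size did depend on the control for cholesterol synthesis, with medians of −1.22 against shScr1 and −0.42 against shScr2, the latter smaller than the −0.64 between the controls. The contractile and YAP lists, which also differed between the scrambled groups, were not put to that check. In camera with its preset correlation the contractile list passed against either group. The YAP list passed against shScr1 (adjusted p = 0.000742) and not against shScr2 (adjusted p = 0.0991), so the choice of the scrambled group stays open for it. What separated the scrambled groups stays open, because the labels give both the same genotype.

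Rplp0 and Rpl29, which is not on the list, were far lower with miR-128 than the other measured members of the ribosomal protein list. Ribosomal protein genes off the list were not compared. A faulty probe is argued against for Rpl29, whose next brightest probe was at −3.46. For Rplp0 the other probe was at −0.66 and near background, so a faulty probe and a real fall cannot be told apart. The lowest other member of the list was at −1.46, and 11 of its 21 measured members were lower. This was known when the check was chosen, so the check restates the pattern and decides nothing about a shared fall. No biological explanation was tested.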

How the results depend on the processing

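The mean over the probes of a gene was the only setting chosen after the data were seen. The contractile list kept its direction and passed under every setting it was run with but the estimated correlation (1.37, adjusted p = 0.127), with a median of 0.56 without a detection filter. Lists were not run on all probes. Of 26 lists, 8 passed in camera, 0 with an estimated correlation and 16 with fry, which does not compare a list with other genes. The count between the scrambled groups, 8, was 42 with normexp background, 29 without background correction, 4 with median scaling, 19 with the authors' values, 54 with trend and robust, and 1 with the replicate block. The block ended the calls of Cyc1 and Ndufa1 as well and changed no other call of a named gene against both groups or of a list. The count against shScr1 was 1354 with median scaling. With 1 array left out, the counts ran from 1260 to 3338 against both scrambled groups, 284 to 3160 against shScr1, 330 to 2908 against shScr2, and 0 to 362 between the scrambled groups, where 507 to 605 genes had an unadjusted p under 0.05 in limma at a count of 0. A group left with 1 array was assumed to vary like the others. Fewer arrays leave fewer degrees of freedom, which can lower a count but does not by itself raise one. Counts rose only where a miR-128 array was left out, and fell wherever a scrambled array was left out. A spread shared over the groups goes that way, since the SD of the difference between replicates was 0.524 in mir128 against 0.277 in shScr1 and 0.304 in shScr2. How far it accounts for the changes was not tested. The direction of the test turned only for values not past the threshold in the first run, and medians of other such lists changed sign while their test did not. The test turned for Klf4 (0.062 with median scaling, and −0.41 to 0.13 with 1 array left out), Bmi1 (0.11 with median scaling, and −0.84, past the threshold without mir128 replicate B, to 0.41), the matrix protease list (its test turned down at a median of 0.13 with median scaling; −0.0054 to 0.18 with 1 array left out) and the oxidative phosphorylation list. For the last, the test turned up at medians of 0.040 with trend and robust, the replicate block and fry, 0.036 with normexp background, 0.030 without background correction, 0.019 with the authors' values, 0.025 without a detection filter, and 0.055 with detection on all 6 arrays. With 1 array left out its median ran from −0.027 to 0.11. The test turned for no list without shScr1 replicate B or without shScr2 replicate B. Signal near background limited dim genes, Tagln, Lmcd1 and Asb2 among them, for which the size of a change depended on the background correction.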

Other observations

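The comparison of histone families was chosen only after the values of H3c7 and H2ac21 were seen. The 12 measured H2ac genes, which encode histone H2A, were all lower with miR-128, with a median log2 change of −1.91 and values from −2.55 to −0.67. Their standard errors ran from 0.14 for H2ac8 to 0.52 for H2ac15, so many of these sizes are imprecise. The SD of the miR-128 arrays was 1.30 for H2ac21, which fell less without miR-128 replicate A. How far the other H2ac values rest on 1 miR-128 array was not checked. Of 11 H2bc genes, which encode histone H2B, 0 changed in limma and the median was 0.14. Of 9 H3c genes 4 were lower (median −0.68), and of 9 H4c genes 1 was higher and 1 lower (median −0.40). Members of a family are near-identical in sequence, so their probes are not independent measurements, and the families were not compared by a test.

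The largest share of the variance over genes, 64.4% on the first principal component, separated the miR-128 arrays from the scrambled arrays. The second, 16.9%, separated shScr1 from shScr2 and also miR-128 replicate A from replicate B. The SD of the difference between replicates A and B was 0.277 in shScr1, 0.304 in shScr2 and 0.524 in mir128.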
